A study of Mus musculus with 2 samples.

How the data were processed

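RNA was taken from V6.5 mouse embryonic stem cells grown on irradiated mouse embryonic fibroblasts. Per the labels' protocols, total RNA was treated with DNase, and polyadenylated RNA and RNA depleted of ribosomal RNA each went into 1 strand-specific library in which dUTP marked the second cDNA strand. The submitters' processing notes name TopHat and the genome build mm9, and the version of TopHat is not given in the sources used here. The deposited file is 1 list of transcripts in BED format with 12 columns for the whole series, and its header names mm9 and calls the list an initial pool. How transcripts were assembled, filtered or combined, and what the name prefixes U, FT, BROAD and WHITEHEAD stand for, is not given in the sources used here. No value per library was used.

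The columns used were the deposited positions, strand, name and blocks. The score column holds whole numbers as deposited by the authors, on different scales for different name prefixes, and it was used only for a stricter selection and in the closing observations. For names starting with U every score is 0. With no read counts the depth behind a transcript is unknown, and intervals over counts of features are Wilson or Clopper-Pearson 95% intervals that cover counting error only.

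Blocks separated by gaps under 30 bp were joined into exons. Transcripts of 1 strand with overlapping spans were merged into loci. A locus had a head-to-head partner when the 5′ end of a plus-strand locus lay 0 to 2000 bp downstream, in plus-strand direction, of the 5′ end of a minus-strand locus. Tail-to-tail partners were defined in the same way for 3′ ends, and overlap needed at least 1 bp. Counts were set against 1000 circular shifts of the minus-strand loci of each chromosome with a two-sided permutation p, except the overlap of exons and of 50% of the shorter locus, and the excess by distance, which used 200 shifts. Pairs were loci that are each other's nearest partner, and head-to-head and tail-to-tail pairs were compared with a two-sided exact binomial test, a comparison added after the counts were seen. Shares were compared with two-sided Fisher exact tests and medians with two-sided permutation tests of 100000 resamples.

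The file has no gene names, and no annotation of mm9 was used here. Genes were named by structure. Each run of intron, exon and intron lengths in a pool transcript with at least 3 exons was looked up on the same chromosome and strand of GENCODE release M21 (GRCm38), and runs listed under a single gene decided the match. No coordinate was converted between builds. Of the 3846 matched genes, 3837 (99.8%) had a difference between their pool and annotation positions shared with a matched neighbour within 50000 bp. Genes with fewer than 3 exons cannot be matched. Whether a noncoding gene is divergent from, antisense to, on the same strand as or apart from a protein-coding gene was read wholly from the annotation, and so describes the annotated gene. The planned class and list comparisons were to run only with gene names of the file's build. The matched form was adopted after the layout of the file was seen and before any matched gene was examined.

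Before the data were examined, the gene lists, the main tests and a first set of alternatives were fixed. Further tests and alternatives were added afterwards, and the closing section names them. The lists were pluripotency (30 genes), lineage regulators (30), fibroblast feeder cells (25), replication histones (20), known noncoding genes (30), housekeeping (20) and polycomb, trithorax and transcription machinery (25), and of the 180 genes 177 have an annotation entry. Benjamini-Hochberg adjustment was made over 6 coding lists, over 7 lists in the pool, over 4 position classes and over 14 gene families. The rule for genes named in the text took, per list, up to 4 members with a head-to-head partner in the pool and up to 2 without, and the 5 head-to-head pairs with the most exons and the 5 with the longest member. For the annotation comparison, a rule set before matched genes were examined took up to 4 coding members per list with the nearest divergent matched gene, the 10 divergent matched genes with the most exons, and all matchable known noncoding genes. A result chosen by this rule is not reported here.

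The procedures were tested on simulated data. For 75005 randomly placed loci the head-to-head count was 0.983-fold of the shifted count (permutation p = 0.59). These loci had no clustering shared by the strands, so the simulation cannot show how such clustering changes counts over the shifts. With 300 planted pairs, the extra loci found were 101% of those planted. Of 5000 annotated transcripts that were moved and trimmed, 98.9% were matched to their own gene and 0% to another. Moving and trimming left every run of intron, exon and intron lengths unchanged, so the 0% was fixed in advance. This simulation cannot show how often a pool transcript of another structure is matched wrongly or missed. Alternatives covered the distance window, allowed overlap of ends, merging into loci, exon number, transcript length, chromosomes, score, the null model, name prefixes and the choice of annotated start, and the stricter score needed 1000 for FT names and at least 10 for BROAD and WHITEHEAD names. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Numba 0.67.0 and Matplotlib 3.10.9.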

Results

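RNA from V6.5 mouse embryonic stem cells, a pluripotent line grown on a layer of irradiated embryonic fibroblasts, was sequenced as 1 polyadenylated library and 1 library depleted of ribosomal RNA. The data analysed here were 1 pooled list of 110003 transcripts on the mm9 genome, with a position, strand and exon blocks for each transcript and no read count, so the depth of the libraries is unknown. The list names no library and does not separate them, so whether each transcript came from these libraries is not known. With 1 library per group, no comparison between polyadenylated and ribosomal-depleted RNA was made. Loci and genes are features of 1 pooled list and not replicates, so each p-value and interval below describes the arrangement of features in that list and carries no error between cultures.

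The pool held mostly short, unspliced transcripts. After blocks separated by gaps under 30 bp were joined, 32887 transcripts (29.9%) had more than 1 exon, and the median summed exon length was 513 nt (quartiles 362 and 842 nt). The transcripts fell into 79052 loci, a locus being the transcripts of 1 strand whose spans overlap, with 39284 loci on the plus strand and 39768 on the minus strand, and 66382 loci held a single transcript. Transcript names had 4 prefixes, whose meaning is not given in the sources used here. Names starting with U made up 79.2% of the pool (87129 transcripts, median 476 nt, 19.2% multi-exon), and names starting with FT made up 10.7% (11825 transcripts, median 1531 nt, 43.2% multi-exon). All 7697 BROAD and all 3352 WHITEHEAD transcripts were multi-exon, with median lengths of 355 nt and 743.5 nt. Of the 2492 distinct introns of WHITEHEAD transcripts, 41.0% were also present in BROAD transcripts (Wilson 95% interval 39.1 to 43.0%), and of the 9884 introns of FT transcripts 81.0% were present in U transcripts (80.2 to 81.8%). The same positions on the other strand matched for 0.0803% of WHITEHEAD and 0.132% of FT introns.

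The genes that could be named in the pool were largely noncoding. Exon and intron lengths of pool transcripts with at least 3 exons were matched to the mouse GENCODE annotation, which named 8767 of 15282 such transcripts (57.4%) as 3846 genes, against 39 (0.255%) when the annotation of the other strand was used. Of the annotated noncoding genes that could be matched, 3293 of 5229 were found (63.0%, Wilson 95% interval 61.7 to 64.3%), against 322 of 18624 protein-coding genes (1.73%, 1.55 to 1.93%). The named genes comprised 1796 lincRNA genes, 1092 antisense genes and 349 processed transcript genes. No member of the coding lists was matched. This covered 26 matchable pluripotency genes, such as Nanog and Pou5f1, 23 genes of the fibroblast feeder layer, such as Col1a1 and Vim, 22 lineage regulators, 18 housekeeping genes and 24 genes of polycomb, trithorax and transcription machinery. The replication histone genes have too few introns for a match and were not assessed. The list can therefore not show how far feeder cells contributed RNA.

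Among 21 well-known noncoding genes that could be matched, 10 were found. They were Xist, which silences an X chromosome, and its neighbour Jpx, together with Airn, Neat1, Hotairm1, Fendrr, Miat, Evx1os, Six3os1 and Dleu2. The other 11 were Tsix, Ftx, the imprinted genes Meg3, Rian, Mirg and H19, and the snoRNA host genes Gas5, Snhg1, Snhg3, Snhg5 and Snhg12. In the pool itself, 1 of the 10 had a head-to-head partner within 2 kb (Dleu2, 325 bp), while Airn and Evx1os had none, and for all other named genes the share was 5.24% (two-sided Fisher exact p = 0.417, adjusted p = 1 over 7 lists).

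The title of the series concerns divergent transcription from protein-coding genes. The first comparison asked how often loci lie head to head, with facing 5′ ends up to 2 kb apart on opposite strands. The reference was the same pool with minus-strand loci shifted along each chromosome. Few protein-coding genes that could be matched were found in the pool (322 of 18624), so this comparison sets loci of the pool against each other. Divergence from protein-coding genes was not measured by it. In the pool, 4077 loci (5.16%, Wilson 95% interval 5.01 to 5.31%) had a head-to-head partner, against 2213 ± 83.1 (SD of 1000 shifts) when minus-strand loci were shifted along each chromosome, a 1.84-fold excess (two-sided permutation p = 0.001, the smallest that the shifts can give). On autosomes and X alone, 3586 of 76912 loci had a partner, and the excess was 1.67-fold (permutation p = 0.001). Within 500 bp the excess in the whole pool was 2.86-fold. The excess was present within each prefix, at 1.88-fold for U, 3.79-fold for FT, 4.66-fold for BROAD and 9.06-fold for WHITEHEAD, the last with 6 loci. Among the multi-exon transcripts alone, 240 loci had a partner (2.46-fold). Permuting strands among the loci of each chromosome, in place of the shifts, gave the opposite direction (0.452-fold, permutation p = 0.001).

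Facing 3′ ends, the tail-to-tail control arrangement, were more frequent than facing 5′ ends in the whole pool and less frequent among spliced transcripts. Tail-to-tail partners were present at 4862 loci (6.15%), 2.21-fold over the shifts, so in the whole pool the excess was not particular to facing 5′ ends. By prefix the tail-to-tail excess was 2.35-fold for U, 1.90-fold for FT, 2.63-fold for BROAD and 13.1-fold for WHITEHEAD (8 loci). It was larger than the head-to-head excess for U and WHITEHEAD names and smaller for FT and BROAD names. Counting only pairs of loci that are each other's nearest partner, 1845 pairs were head to head and 2203 tail to tail, a head-to-head share of 45.6% (Clopper-Pearson 95% interval 44.0 to 47.1%, two-sided exact binomial p = 1.97e-08). Among multi-exon transcripts the counts were 119 head-to-head and 81 tail-to-tail pairs, a share of 59.5% (52.3 to 66.4%, exact binomial p = 0.00872). Without U names the counts were 103 and 55 (65.2%, exact binomial p = 1.66e-04), and for FT names alone 70 and 34 (67.3%, p = 5.34e-04). The head-to-head share of U pairs (44.6%) differed from that of FT pairs (two-sided Fisher exact p = 5.17e-06).

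Spliced head-to-head pairs were concentrated at short distances. The median distance between facing 5′ ends was 614 bp in the whole pool (quartiles 218 and 1238 bp), against 679 bp for facing 3′ ends (262 and 1250 bp). Among multi-exon transcripts it was 198 bp (90.5 and 874.5 bp) for 5′ ends and 923 bp (484 and 1382 bp) for 3′ ends. In that set 32 head-to-head pairs lay under 100 bp apart and 28 between 100 and 200 bp, where tail-to-tail pairs numbered 8 and 0. In the whole pool, loci with a facing 5′ end at most 250 bp away exceeded the shifted loci 3.48-fold, against 3.64-fold for facing 3′ ends. Without U names these values were 7.24-fold and 2.10-fold.

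**Figure D1:**
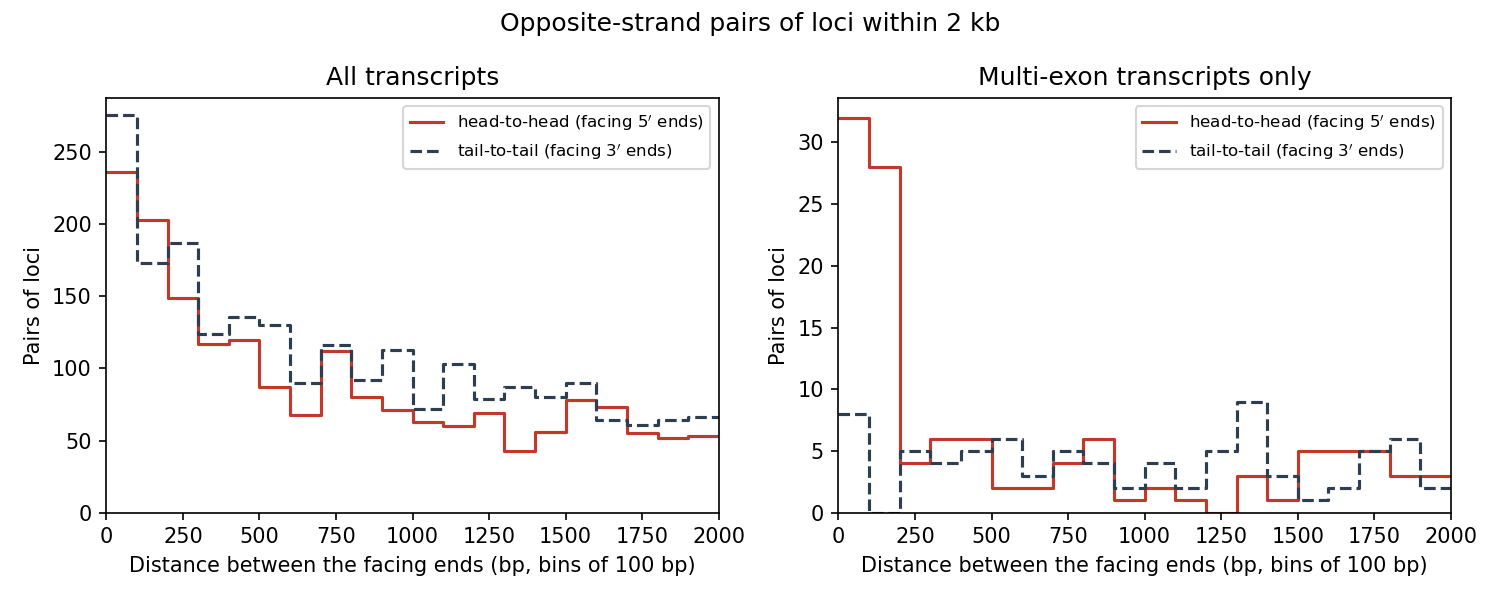
Number of head-to-head pairs (solid line) and tail-to-tail pairs (dashed line) of loci in bins of 100 bp of the distance between the facing ends in bp, for all transcripts (left) and multi-exon transcripts (right). Under 100 bp the multi-exon panel has 32 head-to-head and 8 tail-to-tail pairs.

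Overlap of loci on opposite strands was close to the shifted level in the whole pool, and above it within BROAD and WHITEHEAD names. A locus of the other strand overlapped 6938 loci (8.78%, Wilson 95% interval 8.58 to 8.98%), 1.105-fold over the shifts (permutation p = 0.001). Requiring overlap of exons left 2935 loci, 1.28-fold over 200 shifts (permutation p = 0.005, the smallest they can give). By prefix, overlap of at least 1 bp was 1.07-fold for U and 1.19-fold for FT (permutation p = 0.005 for each). For U names on autosomes and X alone it was 1.02-fold (permutation p = 0.44). Single-exon U transcripts gave 1.02-fold (permutation p = 0.68) and multi-exon U transcripts 1.24-fold (permutation p = 0.001). Single-exon FT transcripts gave 2.16-fold (permutation p = 0.001) and multi-exon FT transcripts 1.145-fold (permutation p = 0.18). Overlap was 3.12-fold for BROAD (161 loci) and 9.47-fold for WHITEHEAD (41 loci, permutation p = 0.001 for each).

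Head-to-head loci of the whole pool differed little from the other loci in splicing and length. More than 1 exon was present in 19.4% of the 4077 head-to-head loci (18.2 to 20.6%) and in 20.3% of the other loci (two-sided Fisher exact p = 0.18). The longest transcript had a median length of 477 nt against 467 nt (permutation p = 0.022 with 100000 resamples), and the genomic span 512 bp against 508 bp (permutation p = 0.59). The length difference missed the threshold of the permutation test at 1000 bp (p = 0.13), with the union of exons (p = 0.092), in multi-exon loci (p = 0.17), in U names (p = 0.24) and among transcripts of at least 200 nt (7 nt, p = 0.24). Within FT names 52.9% of head-to-head loci and 43.1% of the others were multi-exon (Fisher exact p = 0.0251), and the median length was lower in head-to-head loci, 1364 nt against 1614 nt (permutation p = 0.041). Within BROAD names head-to-head loci were longer, with a median of 569 nt against 219 nt (permutation p = 1e-05, the smallest the resamples can give) and a span of 3681 bp against 2038 bp (permutation p = 0.014). The 6 WHITEHEAD head-to-head loci had a median length of 994.5 nt against 405 nt (permutation p = 0.028). Of the 1845 pairs, 112 had 2 multi-exon members, 524 had 1 and 1209 had none, and the median lengths of the longer and the shorter member were 633 nt and 361 nt, described without a test. On the X chromosome 4.90% of loci (4.22 to 5.67%) had a head-to-head partner, and on the autosomes 4.65% (4.50 to 4.81%, Fisher exact p = 0.507).

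The pairs with the most exons and the longest members lay partly on unplaced sequence. All positions are on mm9. A plus-strand locus on chromosome 13 (98204925 to 98285757) held 783 transcripts with up to 15 exons, and its partner started 745 bp away. On chromosome 8 a minus-strand locus (74348540 to 74378200) with 13 exons matched Gm5373 and lay 973 bp from a single-exon partner, and a plus-strand locus (73663223 to 73695355) with 13 exons lay 1077 bp from a partner with 4 exons. Gm12381 on chromosome 4 (38518700 to 38802516) spanned 283817 bp, 15 bp from its partner, and 4930544I03Rik on chromosome 12 (91991576 to 92208238) spanned 216663 bp, 151 bp from its partner. An unnamed locus on chromosome 5 (13619096 to 13764721) spanned 145626 bp. The remaining loci chosen by exon number or span were on unplaced sequence of chromosomes 8 (1 locus, 17 exons) and Y (both with 11 exons).

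Noncoding genes found in the pool were more often divergent from a protein-coding gene than annotated noncoding genes that were not found. A divergent gene has an annotated start up to 2 kb upstream of a protein-coding start on the other strand, measured within the GRCm38 annotation and not from pool positions. Of the 3293 matched noncoding genes 508 were divergent (15.4%, Wilson 95% interval 14.2 to 16.7%), against 188 of 1936 that could be matched and were not (9.71%, 8.47 to 11.1%, two-sided Fisher exact p = 2.48e-09). Each gene was given 1 class, with divergent taken first, then antisense and then same-strand overlap, so divergent genes can also overlap a coding gene. Antisense overlap without divergence was present for 993 (30.2% of all matched genes against 21.7%, Fisher exact p = 2.29e-11). Same-strand overlap without either was present for 15 (0.456% against 5.73%, Fisher exact p = 2.42e-33). In none of these classes were 1777 (54.0% against 62.9%, Fisher exact p = 3.26e-10). With only the outermost 5′ end of each gene counted, the antisense class rose to 1215 (36.9% against 25.8%). Genes matched by BROAD or WHITEHEAD transcripts were divergent in 60 of 168 cases (35.7%, 28.9 to 43.2%), against 448 of 3125 genes matched by U or FT transcripts only (14.3%, 13.2 to 15.6%, Fisher exact p = 3.09e-11, adjusted p = 1.24e-10 over 4 classes). The median distance between divergent starts was 136 bp, taking for each matched noncoding gene the smallest distance over its annotated starts. Distances of named divergent genes below are likewise the smallest over all annotated starts of both genes. With 1 start per gene, its outermost 5′ end, the counts fell to 289 of the matched genes (8.78%) and 109 of the others (5.63%, Fisher exact p = 3.03e-05). For genes matched by BROAD or WHITEHEAD transcripts they fell to 32 of 168 (19.05%), against 257 of 3125 (8.22%, Fisher exact p = 1.6e-05).

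**Figure D2:**
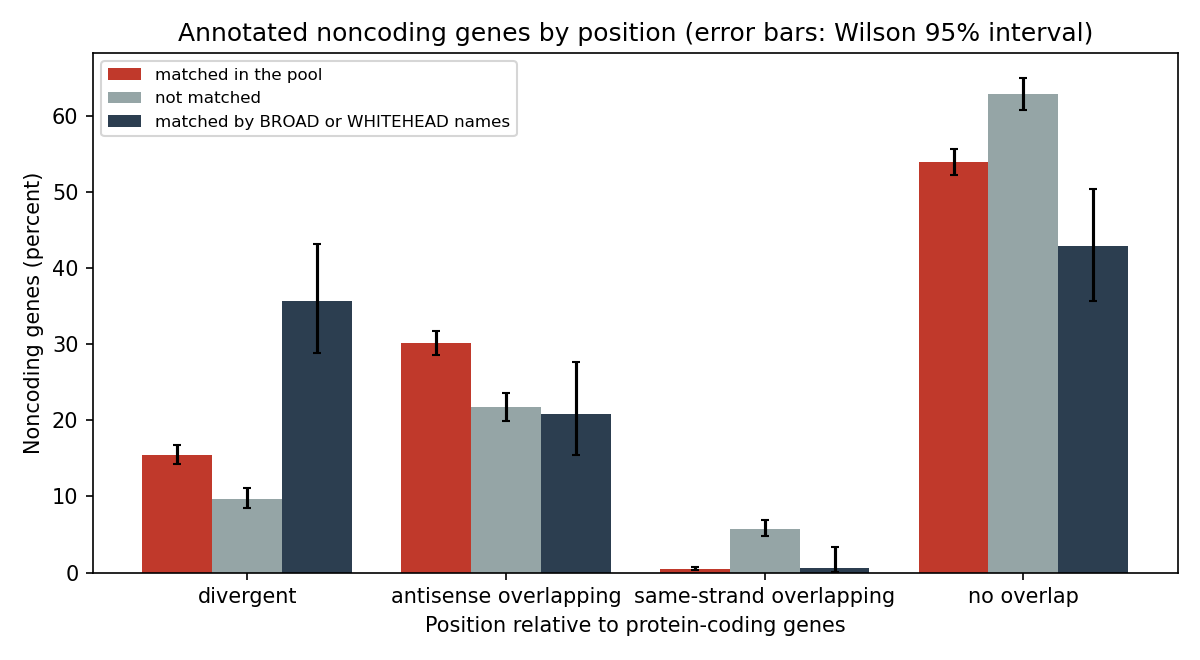
Percent of annotated noncoding genes (vertical axis) in each position relative to protein-coding genes (horizontal axis), for genes matched in the pool (3293), not matched (1936) and matched by BROAD or WHITEHEAD names (168, a part of the matched genes), with Wilson 95% intervals as error bars. The divergent share is 15.4%, 9.71% and 35.7%.

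The divergent noncoding genes with the most exons had named coding neighbours of several kinds. 5530601H04Rik, on the X chromosome (mm9 102234156 to 102274752), was matched by 70 transcripts of all 4 prefixes with up to 11 exons and starts 147 bp from Pbdc1. Gm10634 on chromosome 9 (mm9 88614467 to 88699591) had 25 exons and starts 42 bp from Mthfsl. 9130019P16Rik (14 exons) neighbours Wipf3 at 66 bp, Gm17094 (11 exons) 1700009N14Rik at 46 bp, and 2610316D01Rik (10 exons) the protocadherin gene Pcdh10 at 138 bp. 4930554H23Rik (10 exons) neighbours Otud7a at 222 bp, 4930593A02Rik (10 exons) the ubiquitin ligase gene Siah2 at 189 bp, and F730043M19Rik (9 exons) Atxn7l1 at 96 bp. 4930467D21Rik (8 exons) neighbours Naa11 at 38 bp and 4931419H13Rik (8 exons) the cyclin gene Ccna1 at 187 bp.

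Among the gene lists, regulators of lineage choice most often had a divergent noncoding gene that was found in the pool. This held for 7 of 30 lineage regulators (23.3%, Wilson 95% interval 11.8 to 40.9%), against 2.27% of the other protein-coding genes (two-sided Fisher exact p = 4.24e-06, adjusted p = 2.54e-05 over 6 lists). Evx1, a homeobox gene, and Evx1os start 47 bp apart (Evx1os on GRCm38 chromosome 6, 52308389 to 52314832). Sox17, a regulator of endoderm, and Gm37587 start 120 bp apart (chromosome 1, 4496551 to 4499558), and Sox9, a regulator of cartilage and testis development, and BC006965 start 248 bp apart (chromosome 11, 112663927 to 112781976). Further members, named after their values were seen, were Tbx5 with Gm43050 (748 bp), Nkx2-2 with 6430503K07Rik (1020 bp) and Pax6 with Pax6os1 (1530 bp). Of the partners named here, Evx1os, BC006965 and Pax6os1 were matched by FT and U names and the others by U names only. No lineage regulator had a partner matched by BROAD or WHITEHEAD names, against 0.273% of the other genes. Of the pluripotency genes 0 of 30 had a divergent noncoding gene found in the pool. None of them has an annotated divergent noncoding gene that could be matched, so this count was fixed by the annotation. The other lists had 1 gene each or none, with p-values from Fisher exact tests adjusted over the 6 lists. By these exact tests none differed from the other genes. The members, each with its exact test, were Kdm2b with A930024E05Rik (48 bp, matched by BROAD, FT and U names) among 24 genes of polycomb, trithorax and transcription machinery (adjusted p = 0.662), Fn1 with a gene annotated as Apol7d (135 bp) among 25 feeder genes (adjusted p = 0.662), Ncl with C130036L24Rik (174 bp) among 20 housekeeping genes (adjusted p = 0.662), and 0 of 20 replication histones, which likewise have no annotated neighbour that could be matched.

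The list difference was also present in the annotation. When the background was limited to coding genes with an annotated noncoding neighbour that could be matched, 7 of 8 lineage regulators had a match, against 72.4% of the others (Fisher exact p = 0.457). Such a neighbour is annotated for 2 feeder genes, 2 housekeeping genes and 1 gene of polycomb, trithorax and transcription machinery.

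**Figure D3:**
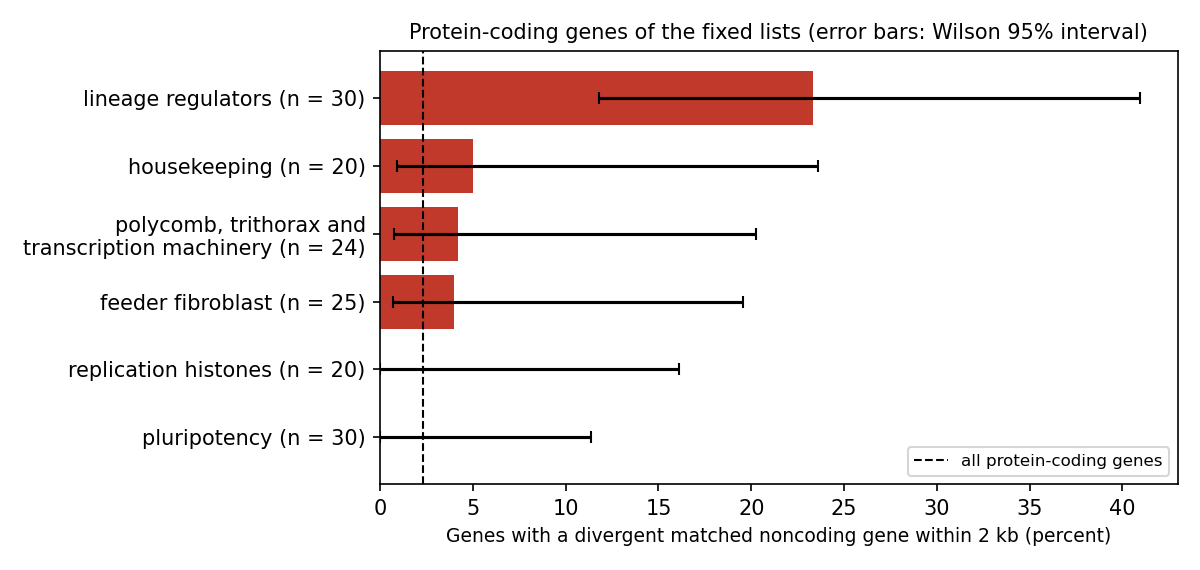
Percent of the protein-coding genes of each list (vertical axis, with the number of genes) that have a divergent noncoding gene matched in the pool within 2 kb (horizontal axis), with Wilson 95% intervals as error bars and the share among all protein-coding genes as a dashed line (2.30%). The lineage regulators stand at 23.3% and the pluripotency genes, none with an annotated neighbour that could be matched, at 0%.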

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

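The score column is outside the comparisons and differed between name prefixes. All of these values were chosen after the column was seen. Of 7697 BROAD transcripts 79.1% had an even score (Wilson 95% interval 78.2 to 80.0%), against 46.8% of 3352 WHITEHEAD transcripts (45.1 to 48.5%). The median score of WHITEHEAD transcripts was 19, and that of BROAD transcripts 4. Among transcripts with at least 3 exons, those matched to an annotated gene had a higher median score than the others in BROAD names (70 against 24, permutation p = 1e-05, the smallest the resamples can give). In WHITEHEAD names the median of the matched transcripts was lower (58.5 against 89, permutation p = 0.0011), but 576 of the 1420 unmatched transcripts lay in the chromosome 13 locus with the most transcripts. Without that locus the direction turned (58.5 against 31, permutation p = 1e-05), as it did with 1 median score per locus (31 against 18, permutation p = 1e-05). In BROAD names both of these alternatives kept the direction (70 against 20 and 26 against 8). What the score measures is not given in the sources used here, and no explanation was tested.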

How the results depend on the processing

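Prefix selections, comparisons of pair shares, the strand permutation of tail-to-tail loci, the overlap of multi-exon transcripts, the removal of transcripts with gaps over 100000 bp, blocks as deposited, lengths and spans at 200 nt or more, and annotation and list alternatives other than the 1 and 5 kb windows were chosen after the data were seen, and the causes of the changes below were not tested unless a smaller set of transcripts or another window makes them. The head-to-head excess over shifts stayed above 1 with p under the threshold in 17 of 18 alternatives (1.34 to 9.06-fold), and permuting strands reversed it (0.452) as it did the tail-to-tail excess (0.539). These 17 alternatives all kept the shifts as the reference, which do not keep clustering shared by the strands. Their number therefore cannot show an excess beyond such clustering. Counts of head-to-head loci followed the window (1673 at 500 bp, 2594 at 1000 bp, 7741 at 5000 bp and 12539 at 10000 bp) and the set: 6187 unmerged ends, 240 multi-exon, 126 of at least 1000 nt, 208 without U, 140 FT, 43 BROAD and 6 WHITEHEAD. Tail-to-tail counts were 2979 at 1000 bp and 8903 at 5000 bp, and overlaps 2935 for exons and 1525 for multi-exon transcripts. The head-to-head share of pairs lost its p at 500 bp (48.0%) and in WHITEHEAD (42.9%), and turned to 59.5% multi-exon, 60.6% at 1000 nt or more, 65.2% without U, 67.3% FT and, without passing the test (exact binomial p = 0.163), 63.6% BROAD. Multi-exon odds ratios crossed 1 at 200 nt or more (1.001), in U (1.03) and in FT (1.48). The length difference of head-to-head loci lost its p at 1000 bp (8 nt), with the union of exons (8 nt), in multi-exon loci (68.5 nt), at 200 nt or more (7 nt) and in U (5 nt), and turned in FT (-250 nt), while it was 350 nt in BROAD and 589.5 nt in WHITEHEAD, and the span difference gained one in multi-exon loci (1368.5 bp) and BROAD (1643 bp). Divergent matched genes numbered 289 by outermost end, 328 for FT, 52 for BROAD and 33 for WHITEHEAD, while the odds ratio against unmatched genes kept its side in 9 of 9 alternatives (1.53 to 3.90). With the annotated-neighbour background the odds ratio was 2.67 for lineage regulators and 0.377 for feeder and for housekeeping genes, and with BROAD and WHITEHEAD matches it was 0 for each of these lists, which says nothing about them because only 0.273% of the other genes then had a partner, while without members whose partners are in the known noncoding list it was 9.34 for lineage regulators. X against autosome odds ratios were 0.885 at 1000 bp, 0.995 at 5000 bp and 0.551 without U. Blocks as deposited made 33.2% of transcripts multi-block. No paired analysis was possible because each group has 1 library and the list does not separate them. Without read counts, depth limits cannot be given.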

Other observations

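Families of developmental transcription factors, chosen after the list results were seen, often had a divergent noncoding gene that was matched in the pool. Of 170 Hox, Sox, Fox, Tbx, Lhx, Nkx, Pax, Irx, Dlx, Gata and sine oculis-related homeobox genes 26 had one (15.3%, Wilson 95% interval 10.7 to 21.5%), against 2.20% of the other protein-coding genes (two-sided Fisher exact p = 2.09e-14). Among 14 families in Fisher exact tests, Sox genes had 5 of 19 (adjusted p = 2.82e-04), Fox genes 7 of 44 (adjusted p = 2.82e-04), the joint group of Lhx, Nkx, Pax, Irx, Dlx, Gata and sine oculis-related genes 7 of 55 (adjusted p = 9.0e-04) and Hox genes 5 of 39 (adjusted p = 0.00447). Examples chosen after their values were seen were Foxf2 with 1700018A04Rik (24 bp), Hoxd1 with Haglr (84 bp), Irx3 with Irx3os (108 bp) and Lhx1 with Lhx1os (125 bp). In the same exact tests olfactory receptor genes had 0 of 1093 (upper Wilson limit 0.350%, adjusted p = 1.55e-10), vomeronasal receptor genes 0 of 329 (adjusted p = 0.00313) and ribosomal protein genes 0 of 76 (adjusted p = 0.595). Annotated neighbours that could be matched were not counted for these 3 families separately, so their counts of 0 may be fixed by the annotation. Zfp zinc finger genes (1.37%, adjusted p = 0.452) and solute carrier genes (2.10%, adjusted p = 1) did not pass the adjusted Fisher exact test, nor did proteasome subunit, NADH dehydrogenase, collagen and protocadherin genes. Tbx genes had 2 of 13 (15.4%), which passed the Fisher exact test before adjustment (p = 0.0349) and not after it (adjusted p = 0.0698). The annotation itself holds this difference, since 18.2% of the 170 genes and 3.06% of the others have an annotated noncoding neighbour that could be matched, and of these 83.9% and 72.0% were matched (Fisher exact p = 0.215).

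Genes of lymphocytes and crowded loci stood out among the named features. All 8 immunoglobulin constant genes that could be matched were found, by U names only. They are heavy-chain genes, among them Ighm (17 transcripts) and Ighg1 (13 transcripts). Of 8 T cell receptor constant genes that could be matched 3 were found, also by U names only. Whether these transcripts came from the sequenced libraries cannot be told from the list. Of the 322 matched protein-coding genes 44.1% have a provisional symbol, against 7.26% of the 18624 that could be matched. The chromosome 13 locus with 783 transcripts (590 WHITEHEAD and 180 BROAD) had 43 distinct introns, and a minus-strand locus on the X chromosome (mm9 47908855 to 47988498) held 480 transcripts, 414 of them BROAD. Unplaced sequence of chromosome Y held 2396 transcripts, 99.9% with U names. WHITEHEAD loci lay on the minus strand in 796 of 1293 cases (61.6%, exact binomial p = 8.49e-17), in 66.0% of those with 2 exons and 47.4% of those with more, while BROAD loci did so in 47.7% (exact binomial p = 0.00147) and U loci in 50.2% (p = 0.273).

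In the patterns that follow, the tests of multi-exon U pairs and of autosomes and X were chosen after their results were seen, and no biological explanation was tested because the list does not separate the groups of the design. The first pattern is the lower number of facing 5′ than facing 3′ ends among U names. Unplaced Y sequence and other unassembled sequence were argued against, since the head-to-head share of U pairs on autosomes and X was 44.3% (exact binomial p = 2.50e-11). A wrong strand in single-exon transcripts was weighed, because the share was 44.6% in single-exon and 59.0% in multi-exon U transcripts (Fisher exact p of the difference 0.00137). The multi-exon interval was 50.1 to 67.4% (Clopper-Pearson 95%, exact binomial p = 0.0465). Wrong strands at random in a minority of transcripts would move the counts of facing 5′ and facing 3′ pairs towards equality and not past it. The single-exon share lay past it (Clopper-Pearson 95% interval 42.9 to 46.3%, exact binomial p = 1.70e-10), which argues against that form. A wrong strand in most single-exon U transcripts was not tested. Single-exon FT pairs did not share the pattern (66.7%, Fisher exact p = 0.0106 against single-exon U pairs). The last explanation was that both ends of 1 cloned RNA were listed as separate transcripts. Its prediction, written before the test, was a larger share of facing 3′ than of facing 5′ pairs inside the span of 1 FT transcript. The share was not larger (5.43% against 6.17%, odds ratio 0.873, 95% interval 0.657 to 1.16, Fisher exact p = 0.381). The interval also holds values above 1, so the explanation stayed open.

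The second pattern is the larger divergent share of genes matched by BROAD or WHITEHEAD names. More annotated starts per gene may account for part of it, since the odds ratio of 3.32 became 2.29 over strata of the number of starts (95% interval 1.62 to 3.24), and this argues against starts as the whole cause. The choice among alternative starts left an odds ratio of 2.63 with 1 start per gene (Fisher exact p = 1.6e-05), and strata of exon number left 3.29 (95% interval 2.37 to 4.58). Differences in expression between the sets of genes were not tested, as the list holds no counts.

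The third pattern is that noncoding genes holding a miRNA or snoRNA gene on their strand were seldom matched, a hypothesis that came from the known noncoding list, where 10 of the 11 unmatched genes and 1 of the 10 matched genes (Dleu2) are such hosts. Of 137 host genes 24.8% were matched, against 64.0% of 5092 others (odds ratio 0.186, two-sided Fisher exact p = 3.94e-20), and without the listed genes 33 of 126 hosts were (odds ratio 0.200, p = 2.47e-17). Gene length was argued against as the cause, with a common odds ratio of 0.183 over 10 strata of gene length (95% interval 0.123 to 0.271). Removal of transcripts that overlap small RNA genes during assembly of the list is consistent with these values, and absence of these RNAs for another reason was not separated from it.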
